A study of Mus musculus with 6 samples.

How the data were processed

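RNA was measured in 6 libraries from NIH-3T3 cells, an established mouse embryonic fibroblast line. Per the labels, the cells were infected with lentivirus carrying Cas9 and 1 of 3 guide RNAs, selected with 2 ug/mL puromycin and used as uncloned pools. The guide R26 sg1 served as the control and is named after the Rosa26 locus, a site that is commonly used as a neutral target. PC sg2 and PC sg5 are named after pyruvate carboxylase, whose mouse gene is Pcx. Each guide had 2 libraries. All cells spent 48 h in medium with 0.2 mM glutamine and 10% dialyzed serum before RNA was extracted with Trizol, and libraries were made from polyadenylated RNA with the NEBNext Ultra kit, a kit that does not mark the strand. The labels do not say whether the 2 libraries of a guide came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The sequences of the guides and the positions of their cuts are not given in the sources used here.

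The submitters' processing notes name bcl2fastq 2.17, Trimmomatic, STAR, featureCounts and DESeq2 as tools and GRCm38 as the mouse genome build. Their settings, the gene annotation and whether counting used the strand are not given in the sources used here. The authors deposited 1 table of normalised read counts, a signal in which each gene's count is divided by a size factor of its library, for 16540 genes and 6 libraries. Within each library, 100% of the values above 0 were whole multiples (tolerance 0.01) of 1 smallest step, so whole reads could be recovered. The reciprocal of that step equalled the median-of-ratios size factor recomputed from the recovered reads. The lowest total of recovered reads for any listed gene was 61 over the 6 libraries, so genes with fewer reads are not analysed here. Such values correct for depth, assume that most genes do not move in 1 direction and are not corrected for gene length, so they compare a gene between libraries but not one gene with another. Gene identifiers were matched by their exact ID to GENCODE mouse release M21, which uses GRCm38, and 16491 of them received a symbol while 49 did not.

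Recovered reads came to 69337013 and 71710049 in the control libraries, 63701586 and 46661048 with PC sg2, and 48897258 and 22895172 with PC sg5. The 3-read floor that this depth allows lay between 2.18 and 6.41 normalised counts per library, and it covers counting error only. Genes with few reads are therefore least precise in PC sg5 replicate 2.

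The tests used limma 3.58.1 in R 4.3.3 on log2(normalised count + 1), with 1 model of 3 groups over all 6 libraries, empirical Bayes moderation with an intensity trend, two-sided tests and Benjamini-Hochberg adjustment. A gene was tested if it had at least 10 normalised counts in at least 2 libraries, which kept 16526 genes and removed 14. The model had 3 residual degrees of freedom and a median of 17.3 prior degrees of freedom. Fold changes are on the log2(value + 1) scale, which understates changes of genes with low counts. An adjusted p under 0.05 counts as past the threshold. The contrasts taken from this model were the mean of both PC guides against control, each PC guide against control, and PC sg5 against PC sg2, which is the direct test of a difference between the guides. No outlier test was made because each group has 2 libraries.

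Before the data were examined, 30 gene lists, the tests, most of the alternatives and a rule for the genes to be named were fixed. Lists with at least 5 tested genes, 28 of them, were tested with camera, which asks whether a list moved more than the other genes, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 28 lists. Each test was repeated with an estimated correlation and with fry, which asks whether the genes of a list moved on balance in 1 direction. The estimated correlation rests on 3 residual degrees of freedom, which leaves little power. A call lost with it therefore does not show that a list did not move. The lists covered the target and control locus, collagens, collagen processing, matrix glycoproteins and proteoglycans, matrix turnover, TGF-beta response and contractile genes, the amino acid response driven by ATF4, and proline, glutamine and aspartate metabolism. They also covered serine and one-carbon metabolism, the TCA cycle and pyruvate metabolism, nuclear and mitochondrially encoded parts of oxidative phosphorylation, glycolysis and hypoxia, sterol synthesis, fatty acid synthesis, the cell cycle, p53 targets, interferon response, cytokines and chemokines, the unfolded protein response, the NRF2 response, lysosome and autophagy, immediate early genes and ribosomal proteins. Markers of adipocytes, muscle, epithelium, leukocytes and macrophages, endothelium, and chondrocytes and osteoblasts completed them.

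The rule names Pcx, Col1a1, Col1a2, Col3a1 and Acta2 whatever their result. For both PC guides against control it adds the 10 highest and 10 lowest log2 fold changes among genes past the threshold with a mean of at least 100 normalised counts and all 4 PC libraries on the same side of both controls. For PC sg5 against PC sg2 it adds the 5 highest and 5 lowest in the same way. Predicted genes with Gm or Rik names and pseudogenes were left out. From each list it takes up to 4 members past the threshold with the smallest adjusted p, or otherwise the member with the smallest p, given as a value. Other genes are said to have been chosen after their values were seen.

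The alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 50 normalised counts, TMM and quantile normalisation, no intensity trend, edgeR 4.0.16 with a quasi-likelihood test and DESeq2 1.42.0 on the recovered reads, only the compared groups in the model, the replicate number as a block, and leaving out each library in turn. Thinning all libraries to the shallowest, removing each library's trend with transcript length and GC content, removing the 50 most abundant genes before scaling, and the count of genes changed at least 2-fold were added after seeing the data. Agreement of the guides was compared with 100 simulations of unchanged groups against shared simulated controls. All 6 libraries, controls included, were drawn from 1 mean per gene, without differences between pools.

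The steps were tested on simulated data with the real means and library sizes, in 5 simulations of 16447 genes with 200 changed genes each. For both PC guides against control, limma recovered 69.0% of the genes changed 1.5-fold and 79.7% of those changed 2-fold, and edgeR recovered 71.7% and 80.9%. With PC sg2 against control limma recovered 67.4% and 76.0%, and with PC sg5 against control 66.8% and 77.2%. False calls over the 5 simulations numbered 19 for both guides against control, 21 for PC sg2 and 24 for PC sg5 with limma, and 39 for both guides with edgeR. Between the guides, where no gene was changed, limma made 0 false calls. The spread of each simulated gene was set by its mean alone, as the intensity trend assumes. These false calls therefore cannot show how the test fares where genes differ in spread. In the list test a raised list was called in 5 of 5 simulations, and 0 of 135 tests of other lists gave a call. Genes were drawn independently there, so this cannot show how the test fares on lists whose genes vary together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.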

Results

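The series asks, per its title, whether pyruvate carboxylase in fibroblasts is needed for collagen production. Pyruvate carboxylase is the mitochondrial enzyme that turns pyruvate into oxaloacetate. RNA from NIH-3T3 pools with the control guide (R26 sg1, n = 2 libraries), PC sg2 (n = 2) and PC sg5 (n = 2) was sequenced after 48 h in 0.2 mM glutamine. Recovered reads ranged from 22895172 in PC sg5 replicate 2 to 71710049 in control replicate 2. The chi-square per degree of freedom between replicates, set against counting error only, was 4.40 for the control, 4.01 for PC sg2 and 3.08 for PC sg5. Across genes, log2 values correlated at 0.994, 0.992 and 0.989 between the replicates of these groups, at 0.988 to 0.993 between libraries of different PC guides, and at 0.958 to 0.963 between control and PC libraries. Genes are not independent replicates in these correlations. The 10 most abundant genes took 6.13% and 6.21% of the counts in the controls and 5.04% to 5.14% in the PC libraries.

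The targeted gene was lower in all 4 PC libraries. Pcx (ENSMUSG00000024892, GRCm38 chromosome 19, 4510472 to 4621752, plus strand, protein coding) had 2914 and 3015 normalised counts in the 2 controls, 316 and 375 with PC sg2, and 713 and 716 with PC sg5. The mean was 2964 ± 71.7 (SD, n = 2) in the control, 345 ± 42.2 (SD, n = 2) with PC sg2 and 715 ± 2.04 (SD, n = 2) with PC sg5. The log2 fold change of both guides against control was -2.58 ± 0.07 (SE), with a limma Benjamini-Hochberg adjusted p of 4.30e-18. The mean of the 4 PC libraries was 17.9% of the control mean. Its exons share no bases with another annotated gene. The transcript at the Rosa26 locus, Gt(ROSA)26Sor, had a log2 fold change of 0.0041 and did not pass the threshold, so 1 of the 2 genes in the list of target and control loci was past it (1 adjusted over the list alone). The libraries measure RNA, and neither the share of edited cells nor the protein is analysed here.

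Both PC guides together against the control address the question of the series most directly. Type I and type III collagen transcripts fell with both guides. Col1a1 went from 269755 ± 12960 normalised counts (SD, n = 2) in the control to 92987 ± 1393 (SD, n = 4) in the PC libraries, a log2 fold change of -1.54 ± 0.02 (SE). Col1a2, the other chain of type I collagen, fell from 306946 ± 10400 to 171705 ± 3374, a log2 fold change of -0.84 ± 0.02 (SE). Col3a1 fell by 1.51 ± 0.03 (SE) on the log2 scale, and Acta2, the smooth muscle actin of contractile fibroblasts, fell by 1.52 ± 0.03 (SE), with 34.8% of the control level left. These 4 genes had limma Benjamini-Hochberg adjusted p-values between 2.76e-22 and 1.23e-19, with all 4 PC libraries below both controls. Col1a1 and Col3a1 lie on GRCm38 chromosome 11 (94936224 to 94953042, plus strand) and chromosome 1 (45311538 to 45349706, plus strand), and Col1a2 and Acta2 on chromosome 6 (4504814 to 4541544, plus strand) and chromosome 19 (34241090 to 34255590, minus strand). All 4 are protein coding.

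**Figure D1:**
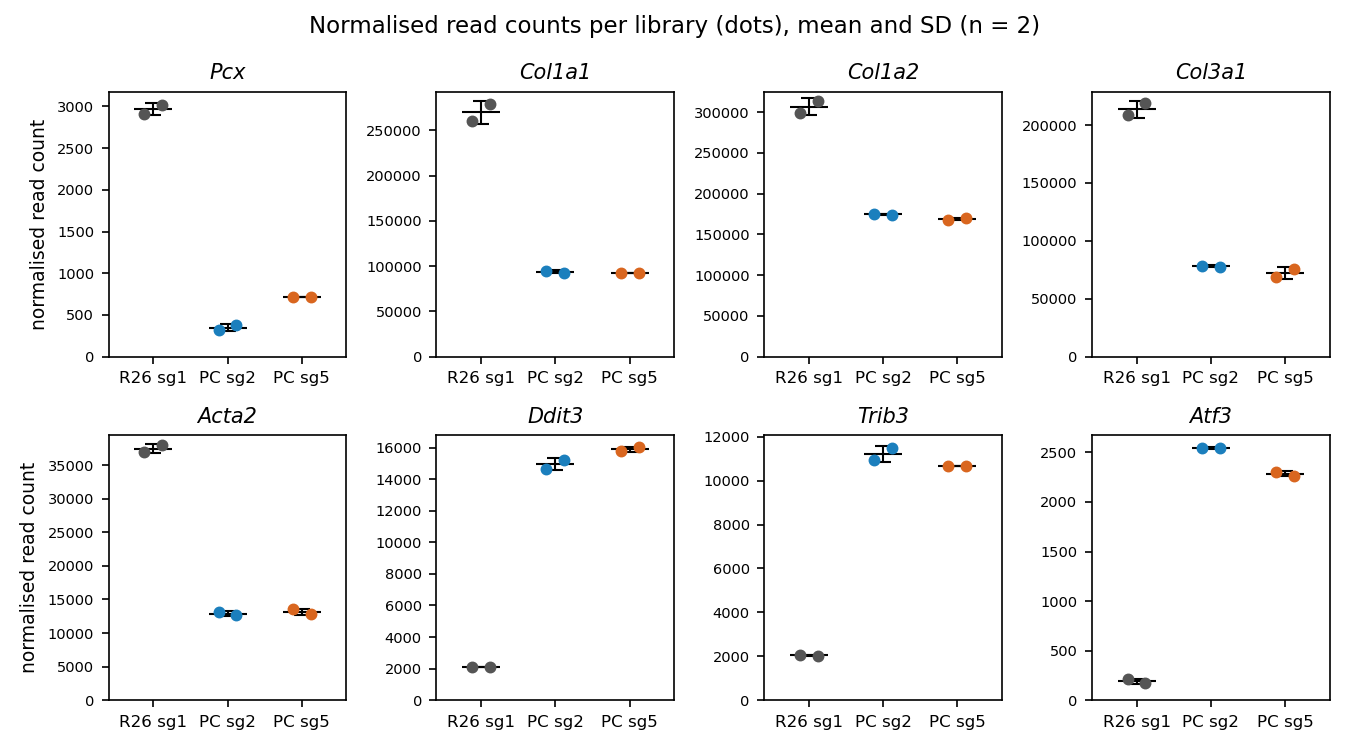
Normalised read counts (vertical axis, starting at 0) of 8 genes in each library, with the guide on the horizontal axis, where dots are libraries and the bars give the mean and SD (n = 2). Pcx lay between 316 and 716 in the PC libraries against at least 2914 in the controls, the 3 collagen genes and Acta2 were lower with both guides, and Ddit3, Trib3 and Atf3 were higher with both.

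In total 11222 of 16526 genes (67.9%) passed the threshold for both guides against control, 5674 higher and 5548 lower, by limma with Benjamini-Hochberg adjustment. Of them, 2944 changed at least 2-fold (1071 higher, 1873 lower). The excess of lower genes among these was smaller under quantile normalisation (1312 higher, 1635 lower) and without the 50 most abundant genes (1176 higher, 1740 lower). With a mean of at least 50 normalised counts, where fewer genes were tested, the count was 1934 (708 higher, 1226 lower). Every gene named as having risen or fallen in the account of this comparison had a limma Benjamini-Hochberg adjusted p of at most 0.0114, from 4 PC and 2 control libraries. With only 2 controls the spread is poorly known, and without control replicate 1 or 2 the count was 9795 or 9738.

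The largest rises under the naming rule were in Serpinf2 (alpha-2-antiplasmin), with a log2 fold change of 4.81 ± 0.23 (SE) and a mean of 221 normalised counts in the PC libraries, the potassium channel gene Kcnj14 (3.71 ± 0.20), the stress-induced transcription factor gene Atf3 (3.68 ± 0.07) and Nog (3.61 ± 0.19), which encodes the BMP antagonist noggin. Rragd, a Rag GTPase of amino acid signalling to mTORC1, rose by 3.58 ± 0.16, and Gadd45a, a growth arrest and DNA damage gene, by 3.43 ± 0.04, from 829 to 8963 normalised counts. Dnah10, Cspg5, Cass4 and the MAP kinase phosphatase gene Dusp4 rose by 3.43, 3.35, 3.34 and 3.26. The largest falls were in Aox3, an aldehyde oxidase (-4.04 ± 0.29), Ptprv (-3.19 ± 0.12), the angiotensinogen gene Agt (-3.14 ± 0.14), Spon2 (-3.08 ± 0.24) and Lrrc17 (-3.05 ± 0.16). Fgf23, Crocc2, the interferon-induced Mx1, the synaptonemal complex gene Sycp2 and Galnt9 had log2 fold changes of -3.00, -2.98, -2.97, -2.89 and -2.88. Without stated use of the strand, reads of overlapping genes cannot be told apart, and such overlap covers 19.1% of the exon bases of Gadd45a and 21.2% of Cass4. Among list members named for this comparison it covers 26.7% for Fdps, 18.8% for Spp1, 17.3% for Sqstm1, 15.6% for Lipe, 15.1% for Aars and between 10.9% and 12.6% for Ddit3, Egfl7, Loxl3, Hmgcs1 and Mcm7.

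Matrix genes were mostly lower. Of 33 collagen genes tested, 23 fell, 6 rose and 4 did not pass, with a median log2 fold change of -0.85. By limma, 29 passed when adjusted over the list alone. Col6a3, Col6a1 and Col12a1 fell by 2.20, 1.94 and 1.94 on the log2 scale. The 6 that rose, named after their values were seen, were Col7a1 (0.61), Col9a3 (1.14), Col4a4 (1.60), Col14a1 (1.79), Col20a1 (1.98) and Col11a2 (2.28), all with under 1000 normalised counts in the control. Of 29 collagen processing genes, 26 fell and 3 rose (median -0.78, 29 adjusted over the list alone), among them the cross-linking enzymes Lox (-1.30 ± 0.03, SE) and Loxl3 (-1.40 ± 0.04) and the procollagen processing genes Pcolce (-1.28 ± 0.02) and Bmp1 (-1.04 ± 0.03). Matrix glycoproteins and proteoglycans had 46 of 51 members lower and 3 higher (median -1.04, 49 adjusted over the list alone), with Sparc, Ltbp2, Ogn and Postn at -1.28, -1.71, -1.78 and -2.24. For matrix turnover 15 of 23 fell and 6 rose (median -0.49, 21 adjusted over the list alone), and the 4 with the smallest p-values, Mmp2, Plat, Serpine2 and Mmp14, fell by 1.30, 1.96, 1.44 and 0.92. Camera with the preset correlation called all 4 lists lower, with Benjamini-Hochberg adjusted p-values of 2.25e-06, 4.05e-09, 6.13e-17 and 0.00242 in that order. Each of these calls was lost with an estimated correlation (adjusted p = 0.247 for collagens and adjusted p = 0.193 for the other 3 lists), a version of the test with little power here.

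Fibroblast and contractile genes moved in both directions. In the list of TGF-beta response and contractile genes 25 of 39 fell, 11 rose and 3 did not pass (median -0.59, 36 adjusted over the list alone). Vim, which encodes the intermediate filament vimentin, fell from 336938 to 132287 normalised counts (log2 fold change -1.35 ± 0.02, SE), the growth factor receptor gene Pdgfra fell by 1.61 ± 0.03 and the tropomyosin gene Tpm1 by 1.01 ± 0.02. Members that rose, named after their values were seen, included Skil (1.60) and Inhba (1.67), known TGF-beta responsive genes. Camera called the list lower with the preset correlation (adjusted p = 0.00242), a call that was lost with an estimated correlation (adjusted p = 0.201).

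Most genes of the amino acid response (ATF4) list rose, and the trigger of their rise was not tested. Of 51 tested members of the ATF4 list, 47 rose, 3 fell and 1 did not pass (median 0.65, 50 adjusted over the list alone). Ddit3, which encodes the stress factor CHOP, rose from 2110 to 15407 normalised counts (log2 fold change 2.87 ± 0.03, SE), Trib3 by 2.42 ± 0.03, the phosphatase subunit gene Ppp1r15a by 2.54 ± 0.04 and the alanyl-tRNA synthetase gene Aars by 1.24 ± 0.02. In serine and one-carbon metabolism 15 of 19 genes rose and 3 fell (median 0.40, 18 adjusted over the list alone), with Mthfd2, Mtr, Shmt2 and Ahcy at 1.21, 1.30, 0.79 and 0.58. That list shares 6 of its 19 genes with the ATF4 list, and its median without them was 0.33. Among 39 lysosome and autophagy genes 23 rose and 11 fell (median 0.14, 35 adjusted over the list alone), with Sqstm1, Atp6v1h and Fnip2 higher by 1.21, 0.91 and 0.92 and Wipi1 lower at -1.23. Camera called these 3 lists higher with the preset correlation (adjusted p = 2.47e-16, adjusted p = 0.000889 and adjusted p = 0.0186), and each call was lost with an estimated correlation (adjusted p = 0.193 for the ATF4 and lysosome lists and adjusted p = 0.303 for the serine list).

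Lipid synthesis genes were lower. All 24 tested genes of sterol synthesis fell, 22 of them at least 2-fold, with a median of -1.64 and 24 adjusted over the list alone. The synthase genes Hmgcs1 and Fdps fell by 2.05 ± 0.03 (SE) and 2.00 ± 0.04, Cyp51 by 1.76 ± 0.03, and Srebf2, the regulator of the pathway, by 1.41 ± 0.03. In fatty acid synthesis 12 of 15 genes fell and 2 rose (median -0.63, 14 adjusted over the list alone), with the desaturase genes Scd2, Fads1, Fads2 and Scd1 at -1.35, -1.11, -1.58 and -0.98. Both lists were called lower by camera with the preset correlation (adjusted p = 3.02e-16 and adjusted p = 8.28e-05), and neither call held with an estimated correlation (adjusted p = 0.193 for both).

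Interferon response genes fell in 42 of 45 cases and rose in 2 (median -1.42, 45 adjusted over the list alone). Stat2, a transcription factor of that response, fell by 1.63 ± 0.04 (SE), Parp14 by 1.91 ± 0.05, Oasl2 by 1.84 ± 0.05 and Gbp2 by 1.95 ± 0.06, and reads of the Oas, Gbp, Ifit and Mx families are uncertain where the counting split them between near-identical copies. Of 30 cytokine and chemokine genes 22 fell and 5 rose (median -0.84, 27 adjusted over the list alone). The complement gene C3, Cx3cl1 and Vcam1 fell by 2.13, 1.94 and 0.94, while Ptgs2, which encodes cyclooxygenase 2, rose by 2.16 ± 0.03. Camera called both lists lower with the preset correlation (adjusted p = 8.23e-15 and adjusted p = 0.000496), and neither call held with an estimated correlation (adjusted p = 0.193 for the interferon list and adjusted p = 0.321 for the cytokine list).

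In the cell cycle list 38 of 51 genes fell, 8 rose and 5 did not pass (median -0.50, 46 adjusted over the list alone). The proliferation marker Mki67 fell by 1.30 ± 0.04 (SE), Top2a by 1.08 ± 0.03 and the cyclin gene Ccnd1 by 1.03 ± 0.03, while Mcm7, a subunit of the replicative helicase, rose by 0.83 ± 0.03. Overlap with other genes covers 23.4% of the exon bases of Ccnd1. Camera called the list lower with the preset correlation (adjusted p = 5.97e-06), a call that was lost with an estimated correlation (adjusted p = 0.247).

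**Figure D2:**
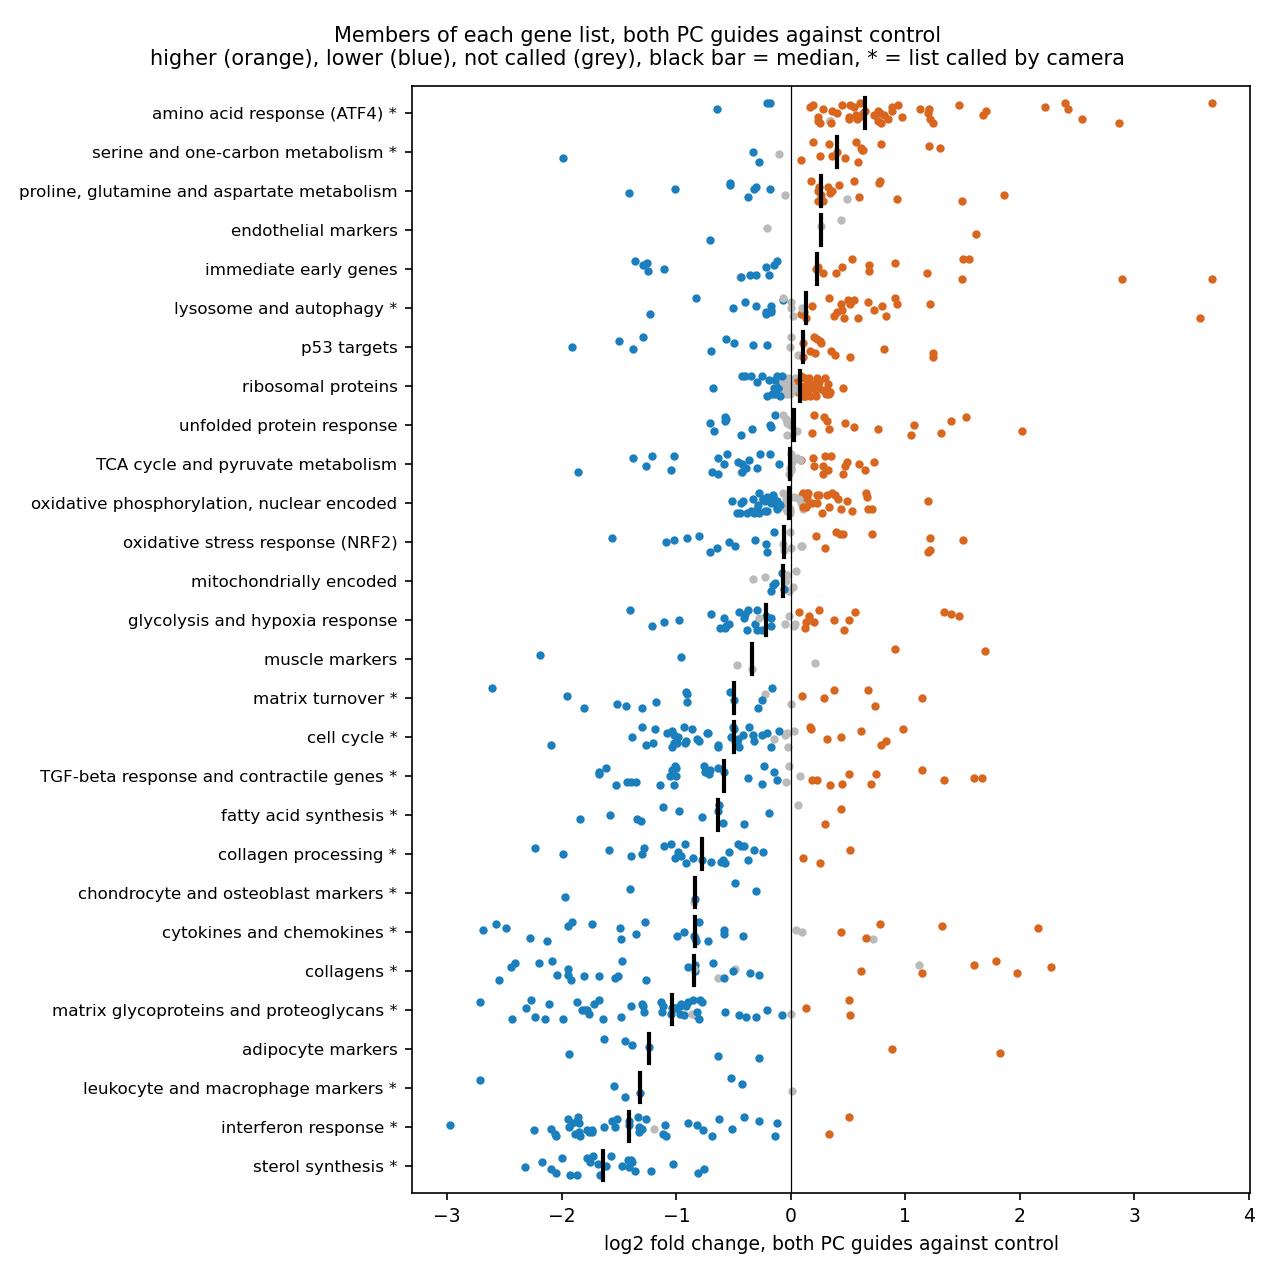
Log2 fold change of both PC guides against control (horizontal axis) for every tested member of the 28 lists (vertical axis), as dots coloured by direction where past the threshold and grey otherwise, with a black bar at the median and a star where camera called the list with the preset correlation. Sterol synthesis had the lowest median at -1.64 and the ATF4 list the highest at 0.65, and with an estimated correlation camera called 0 lists (5 at an unadjusted p under 0.05).

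Central carbon metabolism had no list past the threshold of camera. Of 27 genes of proline, glutamine and aspartate metabolism 17 rose and 8 fell (25 adjusted over the list alone), with the aspartate aminotransferase gene Got1 at 1.49 ± 0.03 (SE), Slc1a3 at -1.41 and Oat at -1.01. Of 44 genes of the TCA cycle and pyruvate metabolism 14 rose and 20 fell (34 adjusted over the list alone), with Idh1, Pdk4, Pdp1 and Acly at -1.86, -1.38, -1.27 and -0.63. Glycolysis and hypoxia genes rose in 13 and fell in 22 of 41 cases (35 adjusted over the list alone), with Ero1l and Hk2 at 1.47 and 1.40 and Gapdh and Pfkp at -0.54 and -1.10. Each of these 3 lists had a camera Benjamini-Hochberg adjusted p of 0.187. Nuclear genes of oxidative phosphorylation rose in 29 and fell in 27 of 72 cases (58 adjusted over the list alone, adjusted p = 0.902 by camera), with Cycs, Uqcrq, Cyc1 and Atp5b at 1.20, 0.67, 0.66 and 0.42, a list median of -0.01, a mean of 0.03 and a camera direction of higher. Of 12 mitochondrially encoded genes 5 fell and 7 did not pass (5 adjusted over the list alone, adjusted p = 0.283 by camera). Among them mt-Co1 and mt-Nd6 had log2 fold changes of -0.16 and -0.18 and were not past the threshold under quantile normalisation. That method gives a gene of unchanged rank the same value in every library, so mt-Co1 (-3.55e-15) could not pass under it. The changes of mt-Nd5 and mt-Nd1 were -0.14 and -0.08 and turned to 0.13 and 0.12 under quantile normalisation. Without control replicate 1, mt-Nd6 (-0.11) and mt-Nd1 (-0.05) were not past the threshold, nor was mt-Nd1 without PC sg2 replicate 2 (-0.05). Without the intensity trend mt-Nd5, mt-Nd6 and mt-Nd1 were not past it, nor was mt-Nd6 with DESeq2 or mt-Nd1 with length and GC trends removed. All of mt-Co1, mt-Nd5, mt-Nd6 and mt-Nd1 were higher in replicate 1 than in replicate 2 of every group, a pattern the main model leaves out.

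Stress and growth lists were mixed. Among 30 unfolded protein response genes 14 rose and 10 fell (25 adjusted over the list alone, adjusted p = 0.309 by camera), with the chaperone gene Hspa5 at 1.53 ± 0.02 (SE), Ern1 at 1.40, Hyou1 at 1.08 and Atf6 at 1.05. Among 29 NRF2 genes 10 rose and 13 fell (24 adjusted over the list alone, adjusted p = 0.760 by camera), with Sqstm1 and Hmox1 at 1.21 and 1.51 and Gstm1 and Fth1 at -1.56 and -0.64. Among 26 p53 targets 14 rose and 9 fell (23 adjusted over the list alone, adjusted p = 0.730 by camera), with Plk2, Aen, Sesn2 and Btg2 at 1.24, 1.24, 0.81 and -1.29, and the list's median was 0.11, its mean -0.09 and its camera direction higher. Of 28 immediate early genes 15 rose and 12 fell (27 adjusted over the list alone, adjusted p = 0.187 by camera). Myc rose from 2788 to 20634 normalised counts (log2 fold change 2.89 ± 0.03, SE), Klf4 by 0.91 and Fosl1 by 1.49, with 57.2% of the exon bases of Fosl1 shared with Ccdc85b. The immediate early list was called higher with edgeR (adjusted p = 0.00454) and DESeq2 (adjusted p = 0.000872) statistics, and the unfolded protein response list with DESeq2 (adjusted p = 0.0420), where over all alternatives run with camera the adjusted p ranged from 0.000872 to 0.494 and from 0.0420 to 0.803. Of 77 ribosomal protein genes 42 rose and 20 fell (63 adjusted over the list alone, adjusted p = 0.0955 by camera), with Rpl18, Rps3, Rps6 and Rpl37a at 0.46, 0.32, 0.34 and -0.68. Quantile normalisation, removal of the 50 most abundant genes and leaving out PC sg5 replicate 2 each ended in a camera call of that list as higher (adjusted p = 2.96e-07, adjusted p = 0.00368 and adjusted p = 0.0345), within a range over all alternatives run with camera of 2.96e-07 to 0.809.

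Markers of other cell types were few. Of 7 leukocyte and macrophage markers 6 fell and 1 did not pass (6 adjusted over the list alone), with Mpeg1, Lyz2, Cd74 and Cd14 at -2.71, -1.32, -0.52 and -0.42 from control means of 145, 260, 602 and 889 normalised counts. Of 6 chondrocyte and osteoblast markers 5 fell and 1 did not pass (5 adjusted over the list alone), with Spp1, Runx2, Sox9 and Dmp1 at -0.84, -0.49, -0.31 and -1.97. Camera called both lists lower with the preset correlation (adjusted p = 0.0489 and adjusted p = 0.0186), and both calls were lost with an estimated correlation (adjusted p = 0.247 for the leukocyte list and adjusted p = 0.336 for the chondrocyte list). The leukocyte call was also lost without control replicate 1 (adjusted p = 0.0637), control replicate 2 (adjusted p = 0.0876) or PC sg5 replicate 1 (adjusted p = 0.0644), with the replicate block (adjusted p = 0.0658), a mean of at least 50 (adjusted p = 0.0694), a pseudocount of 5 (adjusted p = 0.0502) and thinning (adjusted p = 0.0980). Both calls were lost with edgeR (adjusted p = 0.285 and adjusted p = 0.0728) and DESeq2 statistics (adjusted p = 0.347 and adjusted p = 0.0803). Over all alternatives run with camera the adjusted p ranged from 0.0234 to 0.347 for the leukocyte list and from 0.00699 to 0.336 for the chondrocyte list. Of 9 adipocyte markers 7 fell and 2 rose (9 adjusted over the list alone, adjusted p = 0.176 by camera), with Lpl, Lipe, Dgat2 and Pnpla2 at -1.94, -1.24, 1.82 and 0.88. Of 7 muscle markers 2 fell and 2 rose (5 adjusted over the list alone, adjusted p = 0.973 by camera), with Ttn, Des, Tnnc1 and Tnni1 at 1.70, -2.19, 0.91 and -0.96, where Tnni1 lost its call without control replicate 1 (-0.69) and Tnnc1 without control replicate 2 (0.57). Of 5 endothelial markers 1 rose and 1 fell (2 adjusted over the list alone, adjusted p = 0.973 by camera), Esam at 1.62, which was not past the threshold without control replicate 2 (1.29), and Egfl7 at -0.71. Only 2 epithelial markers, Krt7 and Cdh1, were tested, and both fell (2 adjusted over the list alone), at -2.22 and -2.18 from control means of 86.8 and 58.1.

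Each guide was then compared with the control on its own, which asks whether the changes depend on 1 guide. PC sg2 changed Col1a1, Col1a2, Col3a1 and Acta2 by -1.52, -0.81, -1.45 and -1.54 on the log2 scale, and Ddit3 and Myc by 2.82 and 2.89 (n = 2 against 2). For PC sg5 the same genes stood at -1.55, -0.86, -1.57, -1.51, 2.91 and 2.89. Pcx had a log2 fold change of -3.10 ± 0.08 (SE) with PC sg2 and -2.05 ± 0.08 (SE) with PC sg5. The list medians were -0.85 and -0.98 for collagens, -0.95 and -1.13 for matrix glycoproteins, 0.66 and 0.66 for the ATF4 list, and -1.68 and -1.61 for sterol synthesis. With PC sg2, 10658 of 16526 genes passed by limma with Benjamini-Hochberg adjustment (5434 higher, 5224 lower), and with PC sg5 10653 (5395 higher, 5258 lower). Camera with the preset correlation called 12 lists lower and 3 higher with PC sg2, and 11 lower and 4 higher with PC sg5, against 0 for either guide with an estimated correlation (6 and 7 lists at an unadjusted p under 0.05, lowest adjusted p = 0.204 with PC sg2 and adjusted p = 0.173 with PC sg5). The calls differed in 2 lists. Leukocyte markers were called lower with PC sg2 (adjusted p = 0.0479) and not with PC sg5 (adjusted p = 0.0648), and ribosomal proteins were called higher with PC sg5 (adjusted p = 0.0194) and not with PC sg2 (adjusted p = 0.269). In the direct test between the guides camera gave adjusted p = 0.684 for leukocyte markers and adjusted p = 9.99e-12 for ribosomal proteins, the latter lost with an estimated correlation (adjusted p = 0.938).

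The calls of the guides overlapped in direction. Of the genes called with either guide, 5007 were higher with both, 4722 lower with both and 0 called in opposite directions. Independent lists of these sizes would share 1774 and 1662, and simulated unchanged groups against shared simulated controls shared at most 0. The simulation held no differences between pools, so it cannot separate an effect of the guides from a peculiarity of the control pool. Across genes, the log2 fold changes of the guides had a Pearson correlation of 0.926, where simulated unchanged groups reached a mean of 0.427 and a maximum of 0.458. The covariance was 0.692 against a simulated 0.0267, a difference of 0.665. Both comparisons share the same 2 controls, too few to give each guide controls of its own with replicates.

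**Figure D3:**
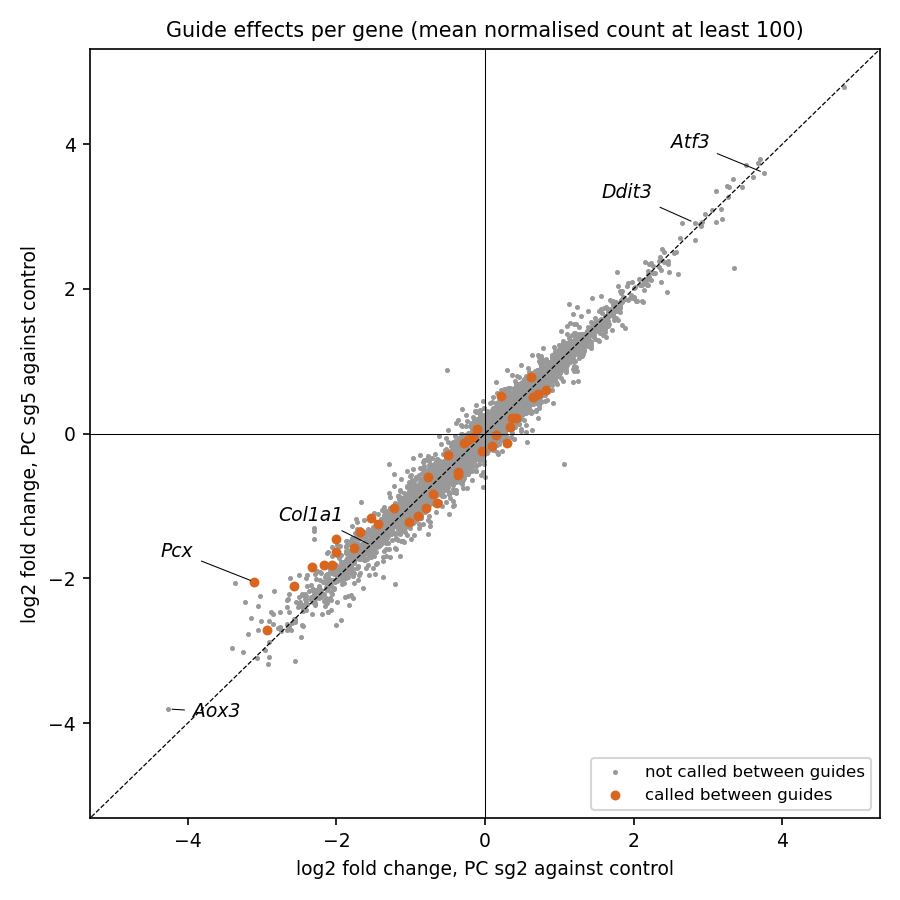
Log2 fold change against control with PC sg2 (horizontal axis) and PC sg5 (vertical axis) for the 11795 genes with a mean of at least 100 normalised counts, where each dot is a gene, the dashed line marks equal change and orange marks genes called between the guides. Pcx lies off the line at -3.10 and -2.05.

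PC sg5 against PC sg2 tests the difference between the guides directly. Pcx was 2.07-fold higher with PC sg5 (log2 fold change 1.05 ± 0.08, SE, n = 2 against 2, limma Benjamini-Hochberg adjusted p of 6.60e-07). Other genes higher with PC sg5 were Col5a3 (0.48), the matricellular gene Smoc2 (0.46), Cxxc5 (0.37) and Olfml3 (0.37). Genes lower with PC sg5 were the receptor phosphatase gene Ptprf (-0.42), Igfbp3 (-0.32), Casc4 (-0.27), the nuclear pore gene Nup107 (-0.25) and Ptk7 (-0.24). The limma Benjamini-Hochberg adjusted p-values of these 9 genes lay between 0.000362 and 0.0467. In total 40 genes passed, 23 higher and 17 lower, and 3 of them differed at least 2-fold. Besides Pcx these were Scn9a (2.34) and Gm11655, named after their values were seen, with means of 5.28 and 0.532 normalised counts with PC sg2. The mean of Gm11655 lies below the 3-read floors of the PC sg2 libraries (2.34 and 3.19), so no size is given for its difference. Col1a1, Col1a2, Col3a1 and Acta2 had differences of -0.03, -0.05, -0.12 and 0.03 that did not pass. Among genes with a mean of at least 100 normalised counts the SD of log2 fold changes was 0.117 between the guides, against 0.726 for PC sg2 and 0.712 for PC sg5 against control. Over all tested genes these SDs were 0.332, 0.864 and 0.865. Camera with the preset correlation called 5 lists, 4 higher and 1 lower with PC sg5, and 0 with an estimated correlation (1 list at an unadjusted p under 0.05, lowest adjusted p = 0.313).

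At an unadjusted p under 0.05, 1760 genes differed between the guides. The count of 40 came to 25 and 26 without control replicate 1 and 2, 14 and 10 without PC sg2 replicate 1 and 2, and 216 without PC sg5 replicate 1. Its balance turned as well, with more genes lower than higher in DESeq2 (38 higher, 47 lower), with only the compared groups in the model (10 and 20), after thinning (10 and 13), and without control replicate 1 (10 and 15), control replicate 2 (10 and 16), PC sg2 replicate 2 (3 and 7) or PC sg5 replicate 1 (90 and 126). Without PC sg2 replicate 2, 8 of the 9 named genes other than Pcx were not past the threshold, with Nup107 the exception and Col5a3 at 0.31, and 5 of the 9 were not without control replicate 1, control replicate 2, PC sg2 replicate 1 or PC sg5 replicate 2. Without the intensity trend of limma 0 genes passed, Pcx included (adjusted p = 0.328, range 1.69e-10 to 0.328 over the 19 alternatives that gave one), with 1241 at an unadjusted p under 0.05. By comparison edgeR called 68 and DESeq2 85, where DESeq2 gave no adjusted p for 12495 genes, Pcx among them.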

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

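Among the tests in this part, those on separate drift of each pool and on the number of control pools were chosen only after the result was seen, and thinning, the length and GC correction and removal of abundant genes were added after the data were seen.

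The guides differed from each other by the direct test of PC sg5 against PC sg2 in 40 genes (limma, Benjamini-Hochberg). The log2 fold changes were 1.05 for Pcx, 0.48 for Col5a3, 0.46 for Smoc2, 0.37 for Cxxc5, 0.37 for Olfml3, -0.42 for Ptprf, -0.32 for Igfbp3, -0.27 for Casc4, -0.25 for Nup107, -0.24 for Ptk7 and 0.17 for Rpl37a (n = 2 against 2). Without PC sg2 replicate 2 the count was 10, and without PC sg5 replicate 1 it was 216. Camera with the preset correlation also separated the guides in 5 lists, whose median differences were -0.031 for matrix glycoproteins and proteoglycans (adjusted p = 0.000789), 0.064 for nuclear genes of oxidative phosphorylation (adjusted p = 6.47e-14), 0.066 for sterol synthesis (adjusted p = 0.00447), 0.053 for the interferon response (adjusted p = 0.0366) and 0.031 for ribosomal proteins (adjusted p = 9.99e-12). With an estimated correlation the adjusted p = 0.313 for oxidative phosphorylation and adjusted p = 0.938 for the other 4.

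Pcx reads fell with both PC guides and differed between them. Thinning all libraries to the shallowest left the difference between the guides at 0.99 against 1.05. Thinning keeps the expected ratio of a gene with as many reads as Pcx, so it could not decide on depth. The 91 measured genes within 1 Mb of Pcx had a median difference between the guides of 0.010 (SE 0.03). This argues against loss of that whole segment in more PC sg2 than PC sg5 cells. Chromosome 19 genes had a median against control of -0.046, compared with -0.01 for other chromosomes, which argues against a large shift of the chromosome. At a mean of at least 100 normalised counts its genes had a median of -0.043, with only chromosome 9 lower (-0.075). The highest was 0.084 on chromosome 12, so a small shift stays open. Those 91 genes had a median of -0.23 (SE 0.10) against control. This lay at the 10.3% point of 2819 windows of at least 50 genes (range -0.69 to 0.33). The windows were drawn around single genes and overlap heavily, so that point is no rank among 2819 separate segments. Loss of part of the segment in some cells of both pools may remain. Different shares of edited cells, and different decay of edited transcripts, were not tested and stay open.

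Most genes passed the threshold between both PC guides and the control. Thinning left 10496 calls among 15142 genes still tested, against 11222 of 16526. Thinning keeps the expected ratio of genes with many reads, so for those it could not decide on depth. Without the 50 most abundant genes 2916 genes changed at least 2-fold, against 2944. The deposited values were already scaled by a median of ratios, which a few abundant genes can hardly set. That count could therefore hardly fall, and no conclusion on abundant genes is drawn from it. Among genes with a mean of at least 100 normalised counts, the SD of changes between the guides was 0.161 of that between PC sg2 and control. Over all tested genes these SDs were 0.332 and 0.864. The smaller spread between the guides argues against separate drift of each pool as the whole source. The control is 1 pool with 1 guide, so a peculiarity of that pool cannot be told apart from an effect of the PC guides.

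With both PC guides 23 of 33 collagen genes and 46 of 51 matrix glycoprotein genes fell (6 and 3 rose), and 47 of 51 genes of the ATF4 list rose (3 fell). The 3 list calls by camera were lost with an estimated correlation (adjusted p = 0.247, adjusted p = 0.193 and adjusted p = 0.193). With length and GC trends removed, the 3 lists kept at least 83.4% of their medians (collagens -0.71 against -0.85, matrix glycoproteins -1.03 against -1.04, ATF4 list 0.69 against 0.65), which argues against such bias as the whole source. After thinning they kept at least 99.1%, although fewer collagen genes with low counts were then tested and their median was -1.27. Thinning keeps the expected ratio of genes with many reads, so for those it could not decide on depth. With 1 control pool, an effect of the PC guides cannot be told apart from a peculiarity of that pool.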

How the results depend on the processing

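Thinning, the length and GC correction, removal of the 50 most abundant genes and the count of genes changed at least 2-fold were chosen after seeing the data. For both PC guides against control the count ranged from 9738 to 11424, and the log2 fold change of Pcx from -2.64 to -2.44, over all alternatives. Of 2624 values of 133 genes named against the control, 2609 had the same direction and side of the threshold and 13 lost their call. The other 2 reversed under quantile normalisation, mt-Nd5 (0.13) and mt-Nd1 (0.12). That method sets values by rank alone, so these genes stood at a higher average rank in the PC libraries. Col3a1, for example, lay above mt-Nd5 in both controls and below it in all PC libraries. Most of the 133 genes were named for large changes or small p-values in these same data, so their stability was largely set in advance. The number of genes changed at least 2-fold was 1934 with a mean of at least 50 normalised counts, where fewer genes were tested. The count of 40 between PC sg5 and PC sg2 became 65 with a pseudocount of 5, 65 with a mean of at least 50, 0 without the intensity trend (limma, 1241 at an unadjusted p under 0.05), 68 with edgeR, 85 with DESeq2, 160 with the replicate block, 23 after thinning and 64 without the 50 most abundant genes, and from 10 (without PC sg2 replicate 2) to 216 (without PC sg5 replicate 1) when single libraries were left out. The cause was not tested. Leaving out a library leaves its group with 1 library, assumed to vary like the others. No label pairs the replicate numbers, and changes of libraries with the same number correlated at 0.0453, 0.0194 and 0.0317 across genes. Mitochondrially encoded genes still took a larger share of counts in replicate 1 than in replicate 2 of each group. The shares were 1.62% and 1.56% in the control, 1.59% and 1.51% with PC sg2, and 1.60% and 1.54% with PC sg5. An effect of the replicate number on some genes, which the main model leaves out, therefore stays possible. DESeq2 gave no adjusted p between the guides for 12495 genes, Pcx among them (log2 fold change 1.06, unadjusted p of 1.06e-24). Of 192 values of 10 genes named between the guides, 52 lost their call. Of the 15 lists called by camera with the preset correlation, an estimated correlation kept 0 (5 at an unadjusted p under 0.05), while fry, which asks another question, called 25. The estimated correlation rests on 3 residual degrees of freedom, which leaves little power. Even sterol synthesis, with all 24 genes lower, had an unadjusted camera p of 0.0258 there. Genes with few reads are limited by the depth of PC sg5 replicate 2.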

Other observations

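The lists in this part, and the test on ribosome biogenesis, were chosen only after the data were seen.

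Genes of ribosome biogenesis rose in 52 of 53 cases with both PC guides, 26 of them at least 2-fold, with 0 lower by limma and 1 not past the threshold. Nop2, Rrp12, Rrs1, Ddx21, Nop56 and the nucleolin gene Ncl rose by 1.69, 1.65, 1.61, 1.45, 1.37 and 1.14 on the log2 scale (n = 4 against 2). The median was 0.97, camera with the preset correlation called the list higher (adjusted p = 1.22e-23), and the call was lost with an estimated correlation (adjusted p = 0.0622). Many of these genes are known Myc targets and Myc itself rose by 2.89, so a Myc response is a candidate explanation of the median of 0.97. It was found on the same data, and the list test restates the rise, so Myc as its cause was not tested.

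Host transcripts of small nucleolar RNAs rose in 12 of 15 cases, 6 of them at least 2-fold, and Snhg18 (-1.20) fell. Snhg1, Zfas1, Snhg12, Snhg5 and Gas5 rose by 1.77, 1.77, 1.59, 1.41 and 0.92, and the list's median was 0.92 (camera adjusted p = 4.03e-05, adjusted p = 0.0932 with an estimated correlation). Several such transcripts are known targets of nonsense-mediated decay, whose factor genes are known to rise when it is slowed. Of 10 factor genes 7 rose, among them Smg8 (0.69), Smg5 (0.65), Smg9 (0.45) and Upf1 (0.39), Upf3a (-0.23) fell and 2 did not pass. Their median of 0.31 was called higher by camera (adjusted p = 0.0199), a call that was lost with an estimated correlation (adjusted p = 0.0932). Slowed decay may be part of the pattern, but raised transcription of the host genes was not tested.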
